A study of Homo sapiens with 5 samples.

How the data were processed

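Total RNA from human skeletal muscle, taken as biopsies of the vastus lateralis (a muscle of the thigh) and combined into a single pool described as insulin sensitive, was hybridised once to each of 5 short-oligonucleotide array designs. These were the HuFL array and the 4 Hu35K arrays, subA to subD, which carry mostly different probe sets (groups of probes that together measure one transcript). The labels name no second pool and no other condition, so no contrast between conditions was made. All 5 arrays were placed in the same group. Their replicate numbers only name arrays (1 for subB, 2 for subA, 3 for subC, 4 for subD and 5 for HuFL), so spreads across arrays are technical and say nothing about differences between people. The number of donors in the pool was not given in the sources used here.

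The deposited values are intensities on a linear scale, as whole numbers with a single value per probe set. The summary software, the background correction and the scaling between arrays were not given in the sources used here. Between 28.7% and 43.5% of the values on an array were below 0, and whether the arrays had been scaled to a common target is unknown. No depth exists for arrays, and their number limits the precision.

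Probe sets were named through the platform annotation supplied with the values. Of 42843 probe sets across the 5 arrays, 29786 had exactly 1 gene symbol, 857 had several and 12200 had none. Gene identifiers of 29711 of the single-symbol probe sets were matched to a RefSeq gene table of the assembly GRCh38.p14, and 0 symbols changed. That table was used for names, no genome build is named for the arrays, and no coordinates were printed. Probe sets with several symbols or none were left unnamed. Control probe sets, meaning spiked bacterial and phage transcripts, human housekeeping controls and any probe set carried by at least 4 arrays, were left out of ranks and bounds. There were 59 of them on all 5 arrays and 18 more on the 4 Hu35K arrays. The name 28S rRNA for one control comes from general knowledge of these arrays. The probe sets of a further human control were left out of the control comparisons and are not reported here.

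Each remaining probe set was given its percentile rank among the non-control probe sets of its own array, and a gene took the median percentile of its probe sets. This gave 14718 ranked genes. A percentile says where a signal lies among the signals of that array, and it does not say that one transcript is more abundant than another, because probes differ in their affinity. Before the data were examined, 24 gene lists were fixed, with 590 different genes, of which 509 were measured. Outdated symbols in the lists were updated through unique synonyms. Each list's median percentile was compared with 100000 random lists of as many genes, drawn with replacement and matched on presence on the HuFL array and on the number of probe sets (1, 2, 3 or at least 4). The permutation test was two-sided, and p-values were adjusted over the 24 lists by the Benjamini-Hochberg method with a threshold of 0.05. The smallest p these permutations can give is 2e-05. Genes within a pathway are not independent, and there is a single pool, so a list p-value describes these arrays and not a population.

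The test was checked on simulated lists, 200 of each size, each called on its p-value before adjustment. With no shift added it called 6.0% of lists of 10 genes, 4.0% of lists of 25 and 4.0% of lists of 50. With 15 percentiles added it called 24.5%, 50.0% and 77.0%, and with 30 percentiles added it called 82.0%, 99.0% and 100.0%. The calls reported below use adjusted p-values, which are never smaller than unadjusted ones. For lists like the simulated ones, these shares are therefore upper limits for such calls. The simulated genes were drawn at random, so the shares do not cover lists whose genes vary together. The adjusted procedure itself was not simulated.

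A noise bound was set for each array as the size of the 1st percentile of its non-control values, a mirror of the negative side. Shares of probe sets above it carry exact Clopper-Pearson 95% intervals. Genes measured on HuFL and on a Hu35K array were compared by Pearson's r and Spearman's rho across genes on log2 intensities floored at 20, with two-sided permutation tests of 100000 permutations, whose smallest p is 1e-05. Dixon's gap was computed for each control probe set carried by 4 or 5 arrays. The spread of readings was taken from log2 ratios of probe sets with the same ID on HuFL and subA, and its 95% range over 5 arrays from the studentized range.

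The rule for the genes named in the text was fixed before the data were examined. From the insulin list it takes members above the 90th or below the 10th percentile, and it adds INSR, IRS1, SLC2A4, AKT2, HK2 and GYS1 whatever their value. From every other list it takes the 4 highest members and the 1 lowest. It also takes the 5 brightest single-symbol probe sets of each array, the human controls, and the 5 genes that disagreed most across arrays. Genes named for their listed value of 0, and the groups in the last part of the closing section, were chosen after their values were seen.

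The alternatives tried were the highest probe set of a gene in place of the median, probe sets without a suffix letter, HuFL alone, the Hu35K arrays alone, unmatched random lists, signals above 0, other noise bounds, other floors, a filter on dim probe sets, scaling by the 75th percentile or the trimmed mean of the middle 96%, and leaving out each array in turn. Leaving out HuFL values of exactly 0 was added after seeing the data. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.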

Results

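RNA from a single pool of vastus lateralis biopsies, described as insulin sensitive, was measured once on each of 5 array designs. HuFL carried 7129 probe sets and Hu35K subA, subB, subC and subD carried 8934, 8924, 8928 and 8928. The median intensity of the non-control probe sets was 22.5 on HuFL, 85.0 on subA, 18.0 on subB, 27.0 on subC and 47.0 on subD, in deposited array units. Values below 0 made up 32.1%, 28.7%, 43.5%, 35.3% and 35.1% of them in the same order. There are no replicates of any array, so single intensities have no error, and no group exists against which this pool could be compared. The comparisons below ask where the signals of named gene groups lay within this muscle RNA, and how far the arrays gave like readings of it.

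Genes of the contractile apparatus had signals near the top of their arrays. Among 19 measured genes used by both fibre types, 12 lay above the 90th percentile, and the median was 97.2 against 36.1 to 69.0 for 95% of random lists. TCAP, a protein of the sarcomere's Z-disc that binds titin, read 13570 on subD. MB, the oxygen-binding protein myoglobin, read 18849 on HuFL, NEB, the giant thin-filament protein nebulin, read 16205 on HuFL, and SMPX, a small muscle protein, read 1810 on subB. At the lower end stood MYBPC1, the slow myosin-binding protein C, which is listed at 0 on its only probe set, as are ACTA1, the skeletal muscle actin, and CKM, the muscle creatine kinase, both chosen after their values were seen. The permutation test gave p = 2e-05, the smallest these permutations can give, and an adjusted p of 8e-05.

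Slow-twitch and fast-twitch contractile genes were both high. Of 10 slow-twitch genes, 6 lay above the 90th percentile, with a list median of 97.0 (random lists 30.2 to 72.6). TNNT1, TNNC1 and TNNI1, the slow troponin subunits, read 22289, 20219 and 12741 on HuFL, and a further TNNT1 probe set read 7916 and a further TNNI1 probe set 941 on subC. MYL3, a slow myosin light chain, read 17312 and 3575 on HuFL, while MYL2, the slow regulatory light chain, is listed at 0. Of 13 fast-twitch genes, 12 lay above the 90th percentile, with a median of 99.9 (random lists 29.8 to 73.3). ATP2A1, the calcium pump of the fast fibre's sarcoplasmic reticulum, read 26144 on HuFL, which made it the brightest single-symbol probe set there. CASQ1, the calcium store protein calsequestrin, read 12368 on subC, MYOZ1, a Z-disc protein, read 11218 on subA and 9577 on subB, and TNNC2, the fast troponin C, read 21850 on HuFL. PVALB, the calcium buffer parvalbumin, was the lowest at 442, below the HuFL noise bound. Both lists had an adjusted permutation p of 8e-05. The slow-twitch call was lost with probe sets without a suffix letter (7 genes, median 83.1, adjusted permutation p = 0.0711), and the difference between the lists was not tested.

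Genes of excitation-contraction coupling, which links the membrane signal to calcium release, had a median percentile of 85.3 over 14 genes, with 4 above the 90th percentile. SLN, sarcolipin, an inhibitor of the calcium pump, read 16723 on HuFL, and JPH1, a junctional membrane protein, read 3293 on subD. RYR1, the calcium release channel, read 4584 on HuFL, 3884 on subC and 1317 on subA. CACNG1, a calcium channel subunit, read 2411 on HuFL and 760 on subC, and FKBP1A, which binds the release channel, was lowest at -224. The adjusted permutation p was 0.0018.

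**Figure D1:**
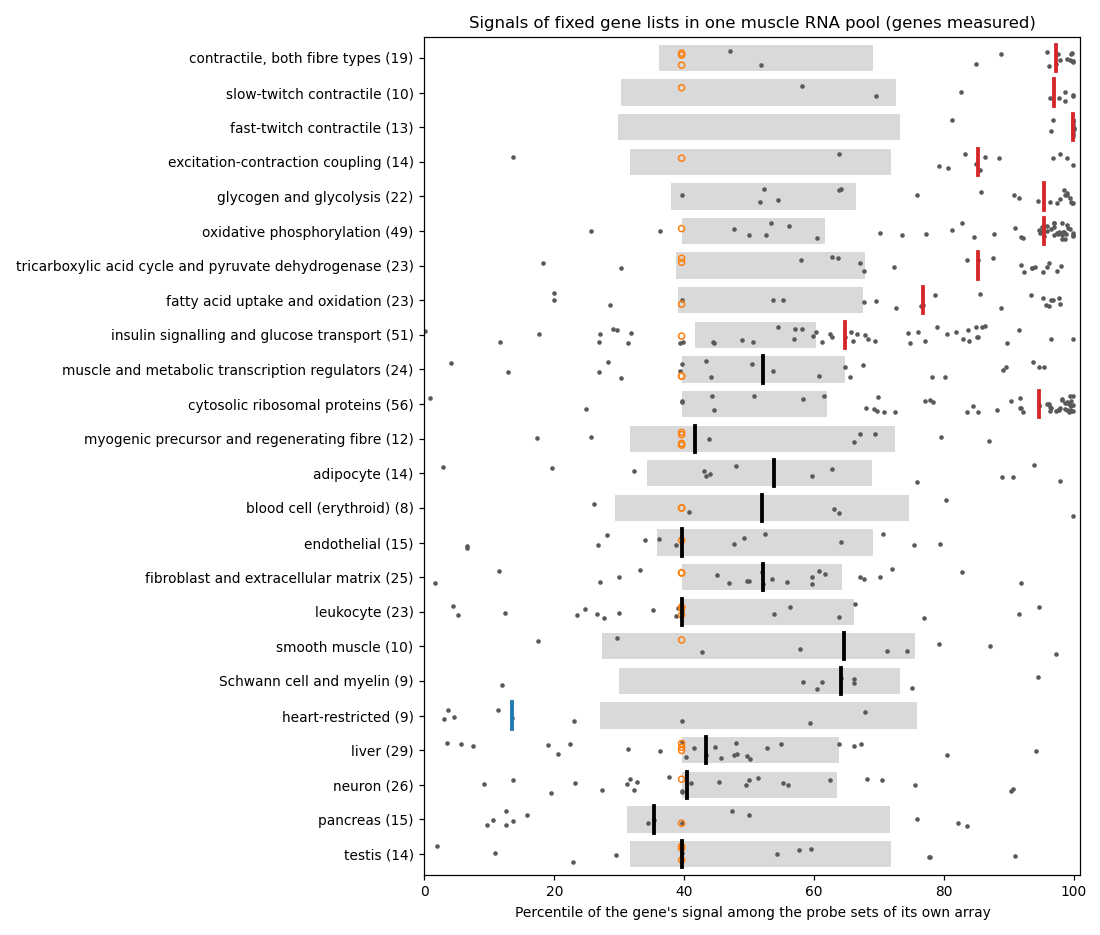
Each grey point is a gene, placed on the horizontal axis at the percentile of its signal among the non-control probe sets of its own array, with the 24 lists on the vertical axis and the number of measured genes in brackets. Grey bands span 95% of matched random lists, bars mark list medians (red higher, blue lower, black not different after adjustment), and orange circles are genes with every probe set listed at 0. Medians ran from 13.5 for the heart-restricted list to 99.9 for the fast-twitch list.

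Genes of energy metabolism were high as groups. Of 22 genes of glycogen and glycolysis, 14 lay above the 90th percentile, with a median of 95.4. GAPDH, ENO3, PGM1 and ALDOA, enzymes of glycolysis and glycogen use, read 16504, 15919, 13577 and 13220 on HuFL, and other GAPDH probe sets read 16359 on subA, 12918 on subC and 449 on subD. GYS1, muscle glycogen synthase, read 1542, just under the HuFL noise bound, and HK2, the insulin-responsive hexokinase of muscle, read -275 on HuFL, 187 on subA and 60 on subC. PGK1, phosphoglycerate kinase, was the lowest, with readings of 39, 39 and 0. Of 49 genes of oxidative phosphorylation, 33 lay above the 90th percentile, again with a median of 95.4. COX7A1 and COX6A2, the muscle forms of cytochrome oxidase subunits, read 18336 and 11105 on HuFL, ATP5ME and NDUFA1, subunits of ATP synthase and complex I, read 12376 and 10359 on subA, and ATP5PB was lowest at -277 and 0. Both lists had an adjusted permutation p of 8e-05.

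The tricarboxylic acid cycle and pyruvate dehydrogenase list had a median of 85.3 over 23 genes, with 10 above the 90th percentile. GOT2 and GOT1, the aspartate aminotransferases, read 5191 and 3795 on HuFL, and MDH2, mitochondrial malate dehydrogenase, read 7408 on subD and 1367 and 384 on subA. SUCLG1, a succinyl-CoA ligase subunit, read 2691 and 1469 on subA and 100 on HuFL, and DLST was lowest at -133. The list of fatty acid uptake and oxidation had a median of 76.8 over 23 genes, with 8 above the 90th percentile. ECH1, ACADM and ECHS1, enzymes of fatty acid oxidation, read 4938, 2785 and 2545 on HuFL, CD36, a fatty acid transporter, read 4247 and 1316 on HuFL and 658 on subB, and UCP2 read -112. The adjusted permutation p was 0.000137 for the first list and 0.00312 for the second. The first call was lost on HuFL alone (19 genes, median 63.4, adjusted permutation p = 0.555) and without replicate 2, the subA array (median 67.0, adjusted permutation p = 0.156).

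The 51 measured genes of insulin signalling and glucose transport lay closer to the middle of the arrays, with a median percentile of 64.7 against 41.6 to 60.3 for random lists. Only 3 genes of this list were above the 90th percentile and 1 was below the 10th. PPP1R3C, which targets a phosphatase to glycogen, read 3343 on subB, TBC1D4, an Akt substrate that controls glucose transporter traffic, read 1575 on subA, and GSK3A, a glycogen synthase kinase, read 883 on HuFL and 332 on subB. Neither GSK3A reading passed its array's noise bound. EIF4EBP1, the translation repressor, read -1461 on subC. INSR, the insulin receptor, had 7 probe sets from -121 to 564, of which none passed its array's noise bound, and IRS1, its docking protein, had 6 from -102 to 595, likewise all under the bound. SLC2A4, the insulin-responsive glucose transporter, read 1748 and 523 on HuFL and 511 on subA, and AKT2 had 4 probe sets from 93 to 574. Of the SLC2A4 and AKT2 readings, only the 1748 passed its bound. At least 1 probe set passed the bound for 9 of the 51 genes. Which readings pass depends on the bound. Another planned bound was each array's highest bacterial control, 301 on HuFL, 239 on subA, 159 on subC and 118 on subD. Above it lay the INSR reading of 564 on subD, but no other INSR reading. So did IRS1 at 595 on subA, 419 on HuFL and 226 and 222 on subC, but not at -102 on subC or 0 on HuFL. All SLC2A4 readings passed it, as did those of AKT2 except 93 on subA.

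The adjusted permutation p for the insulin list was 0.0103, and this call was fragile. It was lost with probe sets without a suffix letter (median 61.2, adjusted permutation p = 0.0713), on HuFL alone (57.9, p = 0.555), with signals above 0 (56.6, p = 0.51) and without replicate 1, the subB array (60.7, p = 0.105).

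Of 24 muscle and metabolic transcription regulators, 3 lay above the 90th percentile and the median was 52.1, not different from random lists (adjusted permutation p = 0.96). MEF2C and MEF2D, muscle transcription factors, read up to 5839 on subD and up to 1648 on subA. RXRA, a nuclear receptor, read 1355 on subD and 0 on HuFL, SREBF1, a regulator of lipid synthesis, read 850 on HuFL, and ESRRA, a nuclear receptor of mitochondrial genes, was lowest at -716. Cytosolic ribosomal proteins had a median of 94.7, with 34 of 56 genes above the 90th percentile and an adjusted permutation p of 8e-05. RPL30 read 15399 on subD, RPL4 7760 on subC, RPL32 17074 and RPS18 15654 on HuFL, and FAU -1100 on subD.

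Markers of other cells that a biopsy can hold did not stand apart from random lists, with adjusted permutation p-values of 0.5 for myogenic precursors (12 genes, median 41.7), 0.824 for adipocytes (14 genes, 53.8), 0.964 for erythroid cells (8 genes, 51.9), 0.39 for endothelium (15 genes, 39.6), 0.89 for fibroblasts and matrix (25 genes, 52.1), 0.377 for leukocytes (23 genes, 39.6), 0.409 for smooth muscle (10 genes, 64.6) and 0.39 for Schwann cells (9 genes, 64.2). HuFL zeros entered these ranks at percentile 39.6, which is the median of the endothelial and leukocyte lists and, below, of testis. Without replicate 5, the HuFL array, the median was 69.0 for myogenic precursors (6 genes, adjusted permutation p = 0.34) and 82.3 for erythroid cells (5 genes, p = 0.0954). With HuFL zeros left out, chosen after seeing the data, it was 63.7 for myogenic precursors (8 genes, permutation p = 0.402 after adjustment). With the highest probe set the medians of fibroblasts, myogenic precursors and endothelium were 81.7, 64.7 and 64.2 (adjusted permutation p = 0.228, 0.916 and 0.603), and with signals above 0 that of myogenic precursors was 68.1 (7 genes, adjusted permutation p = 0.51). Taking the highest probe set also raises random lists, so medians under that rule cannot be set against the main ones. The same holds with signals above 0, where readings at or below 0 were left out before ranking. Single members were bright. HBA2, an alpha globin, read 12056 on subC, while HBB and HBD, beta-type globins, are listed at 0 (chosen after their values were seen). DES, desmin, which skeletal fibres also make, read 3420 on HuFL, GPD1, which muscle also expresses, read 2087 on subA, and CFD, the adipocyte protease adipsin, read 2264 and -617 on subA and 1363 on HuFL. ITGA7, a laminin receptor of muscle, read 1626 on subC and is listed at 0 on HuFL. CD3E, a T cell receptor component, read 1596 on HuFL, just above the noise bound there. LYZ, lysozyme, read 16 to 2897 on HuFL. FLT1, a vascular growth factor receptor, read -46 to 774, both on subB. MAG, a myelin protein, read from 159 on subA to 530 on subC. Of the LYZ, FLT1 and MAG readings, only the highest of each gene passed its array's noise bound. Other high members by percentile were CDH15 (87.0), the myostatin gene MSTN (79.6) and NCAM1 (67.0) among myogenic genes, PLIN1 (90.6) and FABP4 (89.0), lipid proteins of adipocytes, and ALAS2 (80.3), EPB42 (63.8) and CA1 (63.1) among erythroid genes. They were MCAM (75.4), VWF (70.6) and TIE1 (64.2) in endothelium, TIMP2 (91.8), LUM (82.7), FBN1 (72.0) and DCN (70.2) in the matrix list, ITGAX (76.9) and GZMA (66.3) in leukocytes, SMTN (87.1), MYH11 (79.2) and LMOD1 (74.3) in smooth muscle, and SOX10 (94.5), CNP (66.2) and MOG (66.1) in Schwann cells. None of these other members, from CDH15 to MOG, had a probe set above its array's noise bound. At the other end, LIPE read at most -119 on 3 probe sets, FBLN1 at most -709 on 2, CD14 -689, KDR -490, TAGLN -148, S100B at most -132 and AHSP at most -12, and PAX3 lay at percentile 17.3. With the highest probe set of each gene, adipocyte markers came out above random lists (median 87.4, adjusted permutation p = 0.0434) and leukocyte markers below them (39.6, p = 0.00667). Leukocyte markers were also lower with HuFL zeros left out, an alternative chosen after seeing the data (31.8, permutation p = 0.026).

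Among tissues the biopsy should not hold, the heart-restricted list was lower than random lists, with a median of 13.5 over 9 genes against 27.1 to 75.9 (adjusted permutation p = 0.00309). At least 28.7% of each array's values were below 0, so this median lies among negative readings. The call orders such readings and does not measure an absence of heart RNA. GATA4, a cardiac transcription factor, read -864 on HuFL, NPPB, a natriuretic peptide of the heart, read 757 and -12 on HuFL, NKX2-5 read 188, and HAND2 read 16 on subD and -210 on subA. MYL4, an atrial light chain also made in embryonic muscle, read 3461 on subD and 0 on each of 3 HuFL probe sets. The heart call was lost with the highest probe set (40.3, adjusted permutation p = 0.288) and without suffix letters (24.1, p = 0.0713). It was also lost with signals above 0, where 5 genes remained (51.9, adjusted permutation p = 0.971). It turned direction without replicate 5, the HuFL array, where 3 genes remained (69.2, permutation p = 0.588). Lists for liver (29 genes, median 43.4), neuron (26, 40.4), pancreas (15, 35.4) and testis (14, 39.6) were not different, with adjusted permutation p-values of 0.39, 0.218, 0.167 and 0.445. The members with the highest percentiles were APOC3, an apolipoprotein (94.1), F2 (80.5), C9 (67.2) and FGB (66.1) for liver, CHGA, a secretory granule protein (90.7), TH (90.3), GRIN1 (75.6) and INA (70.5) for neuron, SST, somatostatin (83.6), CPB1 (82.1), GP2 (75.9) and CPA1, with a reading of 22, for pancreas, and ODF1, a sperm tail protein (91.0), ACRV1 (77.9), ACR (77.7) and PHF7 (59.5) for testis. Of these highest members, only APOC3 had a probe set above its array's noise bound, at 1348 on subD. The lowest were HPX (3.5), SNAP25 (9.1), PDX1 (9.6) and PRM2 (1.9). Below random lists, liver passed the threshold with the highest probe set (50.5, p = 0.00703 by permutation) and with signals above 0 (31.3, permutation p = 0.0298). So did pancreas without HuFL (13.0, 6 genes, permutation p = 0.0134). With signals above 0 the pancreas median was 57.7 over 7 genes (adjusted permutation p = 0.883), and with the highest probe set the neuron median was 70.9 (adjusted permutation p = 0.916). The highest probe set raises random lists too, so the liver and neuron medians under that rule cannot be set against their main ones. Signals above 0 leave out all readings at or below 0 and rank the rest anew. Medians under that setting cannot be set against the main ones either.

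The 5 brightest named probe sets of each array were as follows. HuFL had ATP2A1 (26144), MYBPC2, the fast myosin-binding protein C (23792), TNNT1 (22289), TPT1 (22161) and TNNC2 (21850). On subA they were RPS27 (18323), MYL1, a fast myosin light chain (16831), GAPDH (16359), PPP2R3A (15894) and NRDC (13516). On subB they were MYOZ1 (9577), CCDC69 (9472), TMEM176A (6362), SAMD10 (4638) and HSPB7, a small heat-shock protein of heart and skeletal muscle (4276). On subC they were CMYA5, a muscle protein (18845), GAPDH (12918), RPS15 (12738), CASQ1 (12368) and HBA2 (12056). On subD they were HSPB1 (21565) and HSPB6 (18051), small heat-shock proteins, MYOM1, the M-band protein myomesin (16346), RPL30 (15399) and LTAP1 (14733).

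Control probe sets carried by every array gave like readings for some transcripts and different ones for others. The GAPDH 3' probe set read 18162 ± 1150 (SD, n = 5 arrays), a highest-to-lowest ratio of 1.17, and the Alu repeat read 16112 ± 1402, a ratio of 1.23. ACTB, beta-actin, read 1434 ± 1053 at its 3' probe set, 3659 ± 1026 at its middle probe set and 6100 ± 3026 at its 5' probe set. The ACTB 3' reading of 128 on subB was below the noise bound there, and over the other 4 arrays the ratio was 3.43. The 28S rRNA probe set read 1828 ± 1036 and CreX-3, a spiked phage transcript, read 12950 ± 5892. TFRC, the transferrin receptor, was above the noise bound on 0 of the 5 arrays at each of its probe sets. Divided by each array's 75th percentile the GAPDH 3' ratio became 2.98, and divided by the trimmed mean it became 5.67. Without replicate 1, subB, the ratio fell from 4.83 to 2.80 for 28S rRNA and from 3.69 to 2.23 for CreX-3, and without replicate 5, HuFL, the 28S ratio was 2.60.

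**Figure D2:**
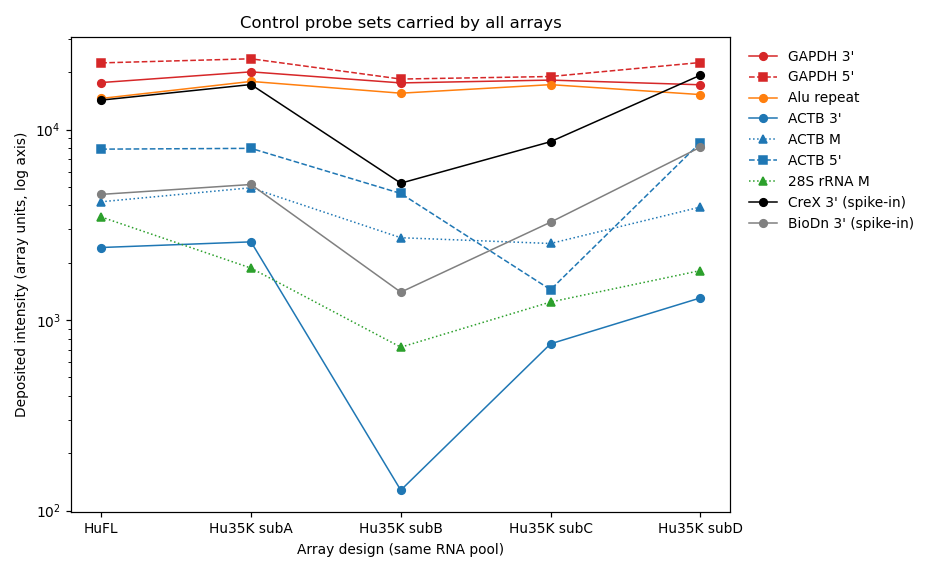
The 5 array designs stand on the horizontal axis and the deposited intensity of 9 control probe sets on the vertical log axis in array units, with 1 reading per point and lines only joining readings of the same probe set. GAPDH 3' stayed between 17207 and 20118, while ACTB 3' ran from 128 on subB to 2576 on subA.

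Probe sets above the noise bound numbered 386 on HuFL (5.46%, exact 95% interval 4.94 to 6.02), 913 on subA (10.3%, 9.68 to 11.0), 260 on subB (2.94%, 2.60 to 3.31), 416 on subC (4.70%, 4.27 to 5.16) and 434 on subD (4.90%, 4.46 to 5.37). These intervals cover counting error only. The counts depended on the bound, and the mirror of the 5th percentile gave 1004, 2568, 879, 1409 and 1397.

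The 5 genes with the widest disagreement between HuFL and the Hu35K arrays were RPS27, RPL41, RPL31 and RPS29, which encode ribosomal proteins, and GNAS. RPS27 read 18323 on subA and RPL41 14114 on subD, and both are listed at 0 on HuFL. RPL31 read 16141 on HuFL and 17 and -252 on subC and subD, RPS29 read 15609 on HuFL and 19 on subC, and GNAS, a G protein subunit, read 11159 on HuFL and at most 165 on 9 Hu35K probe sets. The lower side of all 5 genes was set by the floor of 20, so their order has no meaning. Where the same probe set ID stood on HuFL and subA, 404 IDs not at 0 on HuFL gave r = 0.471 and rho = 0.445 across probe sets (permutation p = 1e-05 for each, the smallest possible). Over 2854 genes on both kinds of array, measured mostly by different probe sets, r was 0.258 and rho 0.192 across genes, which are not independent replicates (permutation p = 1e-05 for each). By array, r was 0.228 for subA, 0.093 for subB, 0.225 for subC and 0.252 for subD, with adjusted permutation p-values of 1e-05, 0.01, 1e-05 and 1e-05 over the 5 relations, and for subB rho was 0.045 with a permutation p of 0.2. Among 58 genes above the noise bound on their arrays r was 0.562, and with probe sets without suffix letters it was 0.127.

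HuFL alone held many values of exactly 0. Including controls, 1057 of its probe sets stood at 0, while the other arrays had 20 to 55. Genes with no other reading than 0 included ACTA1, CKM, MYBPC1, MYL2, SLC25A4, the muscle ADP/ATP carrier, HBB, HBD and the myogenic factors MYOD1, MYF6 and MYOG, all chosen after their values were seen. A value of 0 there is reported only as listed at 0.

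**Figure D3:**
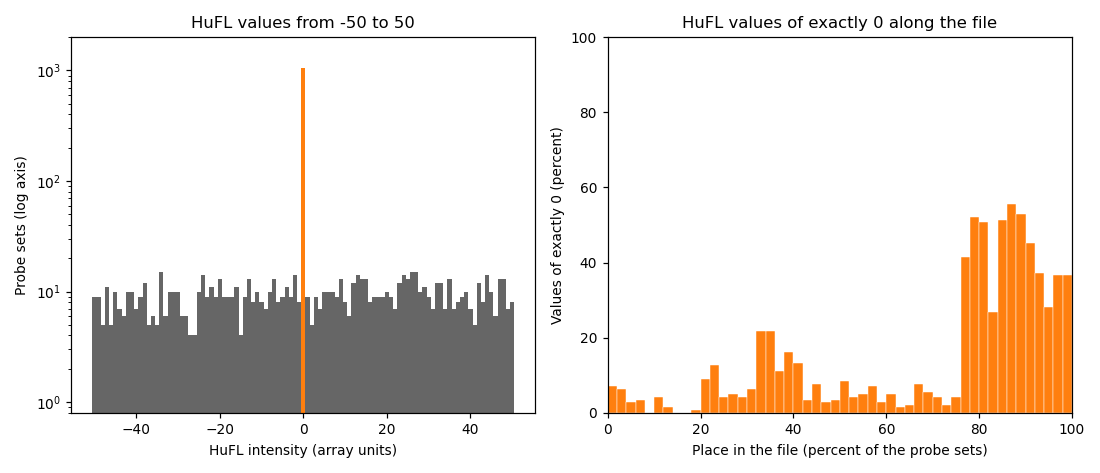
The left panel counts HuFL probe sets (log axis) at each whole-number intensity from -50 to 50 in array units, with 0 in orange. The right panel gives the percent of values at exactly 0 in 50 equal stretches of the file order. In 4 equal parts of that order the shares were 4.0%, 9.5%, 4.5% and, in the last, 41.2%.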

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

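All tests of explanations in this part were chosen after the result was seen. Those on the HuFL zeros were also revised: a test that asked only whether any zero passed the subA bound had gone in favour of failed estimates and was replaced as too weak, the tests by gene were added after the same-ID test had decided nothing, and the share of zeros along the file order served as a criterion in one version and was withdrawn because its value was already known. RNA degraded from its 5' end was tried in 2 forms for the third pattern and then dropped. In the second pattern, a limit of 1.5-fold had at first excluded a scaling factor, by a 3.77-fold range of the ratio of CreX-3 to GAPDH 3', and different spiked amounts. With these values known, the first test was replaced by ratios of unspiked controls, both were set against the spread of readings, which was examined at 5 signal levels, and the requirement for a ceiling was made stricter. Gaps between arrays were tested for 73 control probe sets, 3 were beyond Dixon's critical value, and chance would give about 3.7. The reading of the middle ACTB probe set in the opposite orientation was -82 on subB, apart from the other arrays. On HuFL the middle probe set of the bacterial TrpnX control read -4412. The yeast MMS21 probe set read 80 on subB.

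Probe sets in the opposite orientation, which entered no rank and no list test, also gave signal above the noise bound. The ACTB 3' one read 3115 on HuFL, 2206 on subA, 1665 on subC and 2306 on subD, and the ACTB 5' one read 765 on subA. For GAPDH the 3' one read 1242 on subA, 664 on subC and 1058 on subD, the 5' one read 1002 on subA and 630 on subC, and the middle one read 1421 on subA. The 5' probe set of the bacterial BioDn control read 773 on subA.

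The first pattern weighed was HuFL's values of exactly 0. The design has a single pool, so transcript level was the only biological explanation tested. Ordinary low readings were excluded, since 0 occurred 75.5 times as often as the most frequent other whole number from -20 to 20. Low transcript level as the whole cause was tested by gene on the Hu35K arrays. There 329 genes with only zeros on HuFL lay 6.6 percentiles above 473 genes with HuFL values from -50 to 50 (permutation p = 0.011, adjusted p = 0.044 over 4 level tests). This passed the threshold against that explanation. The adjustment does not cover the tests that were replaced or withdrawn, so the explanation was not decided. By the same probe set ID the zeros differed from others by -3.6 percentiles on subA (permutation p = 0.701) and decided nothing. Failed estimates whatever the level stay open, because the genes with only zeros differed from all other HuFL genes by 2.6 percentiles (permutation p = 0.235). Of probe sets with the same ID on subA, 3.33% of the 60 at 0 on HuFL passed the subA bound against 7.67% of the 404 others (Fisher's exact p = 0.289).

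The second pattern was the narrow range of the GAPDH readings, for which no biological explanation was tested. A single scaling factor per array was not decided. Ratios among the unspiked ACTB 5', ACTB M and 28S middle probe sets varied 3.12-fold to 5.53-fold, and GAPDH was not among them. The spread of same-ID probe sets allows a ratio a 95% range over 5 arrays of 6.82-fold (4 probe sets above 1500) to 11.1-fold (50 above 300). The first range is wide because so few probe sets set it (SD of the log2 ratio 0.37). The second includes probe sets dimmer than these controls (SD 0.87). The test could therefore hardly exclude a scaling factor. Different amounts of spiked transcript stay open as well, since the unspiked ACTB and 28S middle probe sets did not both pass a single reading's range. That range was 3.89-fold above 1500 and 5.47-fold above 300, from the same probe sets and with the same limits. The ACTB one varied 1.96-fold, within it at every level. The 28S one, with a mean of 1828, varied 4.83-fold, within the range at levels 300 and 500 and beyond it from 700 up. A ceiling on bright signals stays open too: the 4 unspiked controls above 10000, 3 of which measure GAPDH, varied at most 1.28-fold, less than each of 4 dimmer ones, while the bright spiked CreX-3 and CreX-5 varied 3.69-fold and 4.26-fold, CreX-3 read 19316 on subD, above GAPDH 3' there, and HuFL readings reached 26144. Scaled by the trimmed mean, GAPDH 3' varied 5.67-fold, so the pattern depends on taking the deposited values as they are.

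The third pattern was the beta-actin 3' probe set reading below the 5' and middle ones. No biological explanation was tested. RNA degraded from its 5' end would lower 5' readings and so acts against this pattern, whatever the state of the RNA, which was not measured here. Cross-hybridisation of coding-region probes to skeletal actin could not be decided: the median 3' to middle ratio was 0.33, the only ACTA1 probe set is listed at 0, and no probe sequences were used here. The ACTB 3' probe set in the opposite orientation read 0.86 to 2.22 times the 3' one, and above it on every array but subA. On subB both readings were under the noise bound. How specific the 3' readings are was not tested.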

How the results depend on the processing

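All values but those with HuFL zeros left out were planned before the data were examined. Of 24 lists, all 24 stayed on the same side of the threshold with unmatched random lists and without replicates 3 and 4. Lists past the threshold also kept their direction there, which was not compared for lists not past it. With the highest probe set, adipocyte (87.4) came past the threshold above random lists. Leukocyte (39.6, the same median as in the main run) and liver (50.5) came past it below random lists. Heart (40.3) was no longer past it. Without suffix letters, calls were lost for slow-twitch (83.1), insulin (61.2) and heart (24.1). HuFL alone lost the tricarboxylic acid cycle (63.4) and insulin (57.9), and the Hu35K arrays alone turned heart to 69.2, with 3 genes left, and brought pancreas (13.0) past the threshold. With signals above 0, insulin (56.6) and heart (51.9) were lost and liver (31.3) gained, and with HuFL zeros left out, chosen after seeing the data, leukocyte (31.8) was gained. With no call gained or lost, medians also moved to 57.7 for pancreas and 68.1 for myogenic precursors with signals above 0, to 81.7 for fibroblasts, 70.9 for neuron, 64.7 for myogenic precursors and 64.2 for endothelium with the highest probe set, and to 63.7 for myogenic precursors with HuFL zeros left out. The highest probe set raises random lists too: transcription regulators, at 76.9, were not different from them (adjusted permutation p = 0.916). Medians under that rule therefore cannot be set against the main ones. Nor can medians with signals above 0, where readings at or below 0 were left out before ranking. Leaving out each array in turn, medians ran from 60.7 to 71.4 for insulin, 67.0 to 86.0 for the tricarboxylic acid cycle, 11.4 to 69.2 for heart, 13.0 to 39.6 for pancreas, 39.6 to 69.0 for myogenic precursors and 39.6 to 82.3 for erythroid cells, the last 2 with no call gained. The counts of probe sets above the bound moved with every bound: for HuFL, subA, subB, subC and subD the mirror of the 5th percentile gave 1004, 2568, 879, 1409 and 1397, the highest bacterial control gave 1740, 2617, 1741, 1472 and 3021, and a fixed 200 gave 2199, 2943, 1290, 1166 and 2205. Highest-to-lowest ratios divided by the 75th percentile became 2.98 for GAPDH 3', 2.05 for 28S and 2.24 for CreX-3, and divided by the trimmed mean 5.67, 2.25 and 2.16, with 3.69 for ACTB M. Leaving out each array, they ran from 2.60 to 4.83 for 28S and 2.23 to 3.69 for CreX-3. The agreement r stayed above 0 in every alternative, from 0.127 to 0.562. Apart from the smaller number of genes in the Hu35K heart list, the cause was not tested. Signal over background limits the readings below the bound, and between 2.94% and 10.3% of an array's probe sets passed the main one, a share that depends on the bound.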

Other observations

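Groups not among the fixed lists were chosen after the brightest probe sets had been seen, and all tests in this part were set then. Proteasome subunits, which degrade marked proteins, had a median percentile of 78.5 over 33 genes, 8 of them above the 90th percentile, with PSMB6 at 3284, PSMA4 at up to 2733 and PSMC3 at 2344. Mitochondrial ribosomal proteins had a median of 78.3 over 73 genes, with 10 above the 90th percentile, MRPL33 reaching 5440 and MRPL34 2388. Genes with symbols starting in EEF1 or EEF2, which include translation elongation factors and enzymes that modify them, had a median of 86.8 over 11 genes, with EEF1A2, the elongation factor form of muscle and nerve, at 5163 and EEF2 listed at 0. Genes with symbols of IL, a number and at most 1 letter, which are interleukins and some of their receptors, lay lower, with a median of 35.8 over 28 genes, although IL32 read 7338. Adjusted over 8 such groups, the permutation p was 8e-05, 8e-05, 0.00676 and 0.0205 in that order. Mitochondrial carriers (34 genes, 51.8), keratins (37 genes, 39.6) and genes with HLA symbols (17 genes, 55.2) were not different, with adjusted permutation p-values of 0.986, 0.299 and 0.733. The IL median of 35.8 lies among readings near or below 0. HuFL zeros rank at 39.6, which is also the lower limit of the random lists for that group. The IL call orders such readings and does not measure an absence of these transcripts. No group in this part was rerun under the alternatives of the section before.

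A hypothesis from the bright HSPB1, HSPB6 and HSPB7 was that small heat-shock proteins as a group, chaperones that bind unfolding proteins, have high signals in this muscle RNA. Because those genes and CRYAB had already been seen, the test was run on the other 4 members, after a first run on all 8 had also passed. HSPB8 read 1094, HSPB2 reached 1170, HSPB3 read 942 and CRYAA reached 690. Only 2 of these 4 genes had a probe set above its array's noise bound. CRYAA lay at percentile 65.9, with 1 of its 2 probe sets listed at 0. The median percentile of the 4 genes was 92.6 (random lists 20.8 to 81.6, adjusted permutation p = 0.00676 over 8 groups), so the hypothesis may hold for this pool. It rests on 4 genes and a single pool, and no other tissue was used here.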
